A study of Mus musculus with 30 samples.

How the data were processed

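The series holds 30 libraries of IDG-SW3 cells, 18 of untreated cells on 6 days and 12 of the hormone experiment in 4 groups, with 3 libraries in each group. The cells were expanded at 33 °C with interferon-gamma and differentiated at 37 °C without it in ascorbic acid and beta-glycerophosphate. The labels call the replicates biological. The 2 experiments used different library kits, so the tests compare changes between them, not levels. Levels are set side by side only to describe what each experiment detected. Before deposit the submitters aligned the reads with TopHat (version not stated) to mm9 and turned them into the RPKM listed for untreated cells and the counts listed for the hormone experiment, by steps their notes do not give. No alignment was repeated here.

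The 18 files of untreated cells hold RPKM, a unit read from the values. Of the low values tested in each library 34.5% to 47.9% lay within 0.1 of a whole number of reads, so the steps are only partly seen, and rRNA rows make up 71.6% to 88.4% of each sum. The 12 files of the hormone experiment are named as RPKM but hold whole numbers that grow with gene length and reach 2083270 for *Malat1*, where 143205 is the highest RPKM its length allows, and they were read as raw counts. The design named limma on RPKM with edgeR if the files held counts, and that clause was used for the hormone experiment. The rule for named genes, a mean of at least 5 in the higher group, was applied to CPM there. Files with several rows for a gene symbol were reduced to 1 value per symbol, the row with the highest mean for RPKM and the sum for counts, which left 25520 symbols in the untreated experiment and 25410 in the hormone experiment.

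Untreated cells were tested with limma (3.58.1) on log2(RPKM + 0.5) with trended moderation over all 18 libraries (12 residual degrees of freedom), on genes with at least 1 RPKM in at least 3 libraries. The RPKM were used as listed. The hormone experiment was tested with edgeR (4.0.16), quasi-likelihood F tests over all 12 libraries (8 residual degrees of freedom), filterByExpr and TMM scaling, and the difference between the responses was the interaction contrast. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. R was version 4.3.3, and DESeq2 (1.42.0) was an alternative added later.

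Genes named in the text were the largest changes in each direction among called genes whose 3 libraries of a group lay above the 3 of the other, an order that 10% of unchanged genes show by chance, the members of each list with the smallest adjusted p, and a set of bone and vitamin D genes named whatever their result. Some genes that met these rules are not reported here. SE for edgeR changes were derived from the change and the F statistic. Counting intervals and the floor of 3 counts used for groups with 0 counts cover counting error only, not the spread between cultures.

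The 25 gene lists cover osteoblast, osteocyte, mineralization and phosphate, collagen and matrix, matrix protease, cell cycle, Wnt, BMP and TGF-beta, vitamin D, interferon, inflammatory, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, immediate-early, axon guidance, adipocyte, chondrocyte, tendon and muscle, macrophage and osteoclast, endothelial, replication histone, nuclear noncoding and ribosomal protein genes. They were tested with camera at a correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone.

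Sequencing runs were read from the file names of the untreated cells. Replicate 1 of every day shared a run. Replicates 2 and 3 of day 35 were alone in another, so the last step in time is mixed with the run for those libraries. Replicates 2 and 3 of day 3 shared a run with day 7 replicate 2 only, so comparisons with day 3 are partly mixed with the run as well. No run is given for the hormone experiment.

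Background in the hormone experiment was measured from the reads on 1100 olfactory receptor genes, which bone cells are not known to express, as reads per kilobase. It made up 0.753% to 1.10% of the reads in the day 3 hormone libraries, 0.0604% to 0.0831% in the day 3 vehicle libraries and 0.635% in day 35 hormone replicate 2. The subtraction per kilobase covers the 82.8% of tested genes with a known length. Of 9355 genes with at least 1 CPM per kilobase in day 3 vehicle cells, 2804 (30.0%) were listed below 1 RPKM in untreated day 3 cells, and the levels correlated at rho = 0.445.

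In a check with 200 genes multiplied by 2 or 4 in simulated libraries without other change, 4-fold changes were recovered in 94% to 98% of genes for pairs of untreated days, 79% to 81% for pairs of hormone groups and 64% for the difference between responses, and 2-fold changes in 38% to 51%, 36% to 43% and 8%. Between 1.68% and 10.4% of the calls were false. The planted list was found and 0 others were called. Simulated genes were drawn independently, so the check does not cover false list calls from correlation between genes. In the hormone experiment changes were planted only in genes with a mean of at least 1 CPM. Genes left unchanged had the same mean in all groups. The check therefore does not cover changes in genes of lower level, or calls from background that differs between groups.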

Results

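IDG-SW3 cells are a conditionally immortalised mouse line that passes from late osteoblasts to osteocytes in culture. They were followed untreated on 6 days of differentiation: day 3, then weekly from day 7 to day 35 (n = 3 libraries per day). In a second experiment the cells were given vehicle or 100 nM 1,25(OH)2D3, the hormonal form of vitamin D3, for 24 h at day 3 or day 35 (n = 3 libraries per group). The first question was which genes change as osteoblasts become osteocytes, and the second was how the hormone response of early cells differs from that of late cells. Levels are mean ± SD in RPKM for the untreated cells and in CPM for the hormone experiment, and log2 changes are ± SE. The groups, comparisons, tests, gene lists and alternatives were fixed before the data were examined. Any choice made later is named as such.

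Untreated cells carried the transcripts of mineralizing bone by day 35. *Ibsp* (bone sialoprotein) rose from 0.483 ± 0.213 RPKM at day 3 to 45.3 ± 17.6 RPKM (n = 3 and 3, log2 change 5.49 ± 0.34), where the median of all genes tested moved by −0.69. The osteocalcin gene *Bglap* went from 3.39 ± 0.932 to 146 ± 49.7 (5.20 ± 0.33) and the channel gene *Panx3* from 1.37 ± 0.197 to 72.5 ± 23.3 (5.23 ± 0.35). *Alpl* (2.50 ± 0.27), the transcription factor gene *Sp7* (2.79 ± 0.25) and the parathyroid hormone receptor gene *Pth1r* (2.84 ± 0.23) rose as well. So did the phosphate-regulating genes *Smpd3* (2.39 ± 0.24) and *Galnt3* (2.05 ± 0.22). *Col1a1* gained 1.18 ± 0.24 from a high start of 113 ± 18.6 RPKM. Cartilage-type collagens *Col11a2* (4.84 ± 0.39) and *Col2a1* (2.73 ± 0.31) and the stress genes *Trib3* (4.48 ± 0.54), *Asns* (2.18 ± 0.30) and *Ddit3* (1.79 ± 0.36) were also higher at day 35. The protease gene *Prss35* reached 196 ± 80.3 RPKM from 4.21 ± 0.262 (5.30 ± 0.27).

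Proliferation and interferon transcripts were lost over the same interval. Interferon-gamma and the lower expansion temperature both ended when differentiation began. Time since that switch is not separable from differentiation in these falls. *Mki67* fell from 30.4 ± 4.80 RPKM at day 3 to 1.90 ± 0.843 at day 35 (n = 3 and 3, log2 change −3.73 ± 0.25), and *Top2a* changed by −3.15 ± 0.24. The linker histone gene *Hist1h1a* dropped from 1326 ± 115 to 83.3 ± 33.9 RPKM (−4.06 ± 0.28). The class II antigen genes *H2-Aa* (96.4 ± 6.45 to 1.29 ± 0.245 RPKM, −5.77 ± 0.26), *H2-Eb1* (−5.23 ± 0.32) and *Cd74* (−4.58 ± 0.22) fell. So did the interferon-inducible GTPase gene *Iigp1* (−5.43 ± 0.39). *Ptgs2* went from 58.7 ± 6.23 to 0.898 ± 0.377 RPKM (−5.43 ± 0.23), with falls of *Il1rl1* (−4.99 ± 0.34), *Ctgf* (−4.21 ± 0.25) and *Dusp1* (−4.68 ± 0.22). The contractile genes *Acta2* (−3.22 ± 0.24) and *Tagln* (−3.11 ± 0.30), *Sox9* (−2.03 ± 0.28) and *Pparg* (−2.97 ± 0.25) fell too. Each of these genes kept its direction and its call after the libraries were centred on their medians.

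Of 9933 genes tested in the untreated cells, 5676 differed between day 35 and day 3, with 559 higher and 5117 lower. The whole distribution was shifted down by 0.69, so that centring the libraries gave 2934 higher and 2139 lower genes, and quantile normalization 2587 and 2471. Relative to the shift, *Spp1* rose (centred log2 change 1.54, adjusted p = 4.53e-05), while in the values as listed its change of 0.72 ± 0.32 did not pass (adjusted p = 0.0591). It did pass without day 3 replicate 1 (0.87, adjusted p = 0.0485) or day 35 replicate 3 (1.03, adjusted p = 0.0121), and after rescaling to rows other than rRNA (1.12, adjusted p = 0.000456). With the replicate number as a block it passed as well (0.72, adjusted p = 0.0492). The fall of *Tnfsf11* (−1.03 ± 0.30) was lost on centring (−0.21, adjusted p = 0.455). With the sequencing run in the model 658 genes were higher and 2805 lower. The osteocyte genes *Dmp1*, *Phex*, *Mepe*, *Sost* and *Fgf23* lay under the filter of 1 RPKM, with *Dmp1* at 0.314, 0.556 and 0.152 RPKM in the 3 day 35 libraries.

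The osteoblast list led the rise in untreated cells between day 3 and day 35: of 21 genes tested 13 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 6.22e-18, adjusted p = 0.0715 with an estimated correlation). Mineralization and phosphate genes gained 6 of 13 against 2 falls (6 and 2 adjusted over the list alone, 1.2e-07, adjusted p = 0.144 with an estimated correlation). Unfolded protein response genes gained 8 of 21 against 2 (8 and 2 adjusted over the list alone, 4.44e-08, adjusted p = 0.144 with an estimated correlation). All 35 cell cycle genes (camera adjusted p = 4.64e-11), 34 interferon genes (3.05e-12) and 23 replication histone genes (3.9e-10) fell, as did 21 of 22 immediate-early genes (3.54e-09). The numbers were the same adjusted over the list alone, and each list had adjusted p = 0.144 with an estimated correlation. For the cell cycle and interferon lists, too, time since expansion ended is not separable from differentiation. Inflammatory genes lost 12 of 16 against 1 rise (12 and 2 adjusted over the list alone, 0.0124, adjusted p = 0.479 with an estimated correlation). The osteocyte list, with 11 of its members above the filter, had 3 rises and 5 falls and did not move as a set (0.276).

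Between these ends the changes came in order. The deiodinase gene *Dio2* rose early, from 0.564 ± 0.272 RPKM at day 3 to 13.1 ± 1.87 at day 7 (n = 3 and 3, log2 change 3.70 ± 0.38, all-gene median 0.23). It stood at 76.0 ± 7.32 at day 14, 98.7 ± 34.7 at day 21 and 15.3 ± 8.01 at day 35. *Ctgf* was already down at day 7 (238 ± 23.0 to 9.87 ± 1.08 RPKM, −4.52 ± 0.25), as was *Ptgs2* (−3.97 ± 0.23). *Mki67* did not differ at day 7 (−0.17 ± 0.25) and was lower at day 14 (−1.67 ± 0.25), together with *Top2a* (−1.71 ± 0.24) and *H2-Aa* (−4.60 ± 0.26). *Bglap* and *Alpl* were lower at day 14 than at day 3 (−1.04 ± 0.33 and −1.11 ± 0.27) and higher from day 21 (2.09 ± 0.33 and 0.92 ± 0.27), with *Sp7* (1.73 ± 0.25) and *Ibsp* (1.98 ± 0.34). By day 28 *Ibsp* (5.31 ± 0.34) and *Bglap* (5.02 ± 0.33) had reached most of their final change. The early fall of *Bglap* did not pass without day 3 replicate 2 (−0.86, adjusted p = 0.111), nor did the day 21 rise of *Alpl* (0.83, adjusted p = 0.0569).

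**Figure D1:**
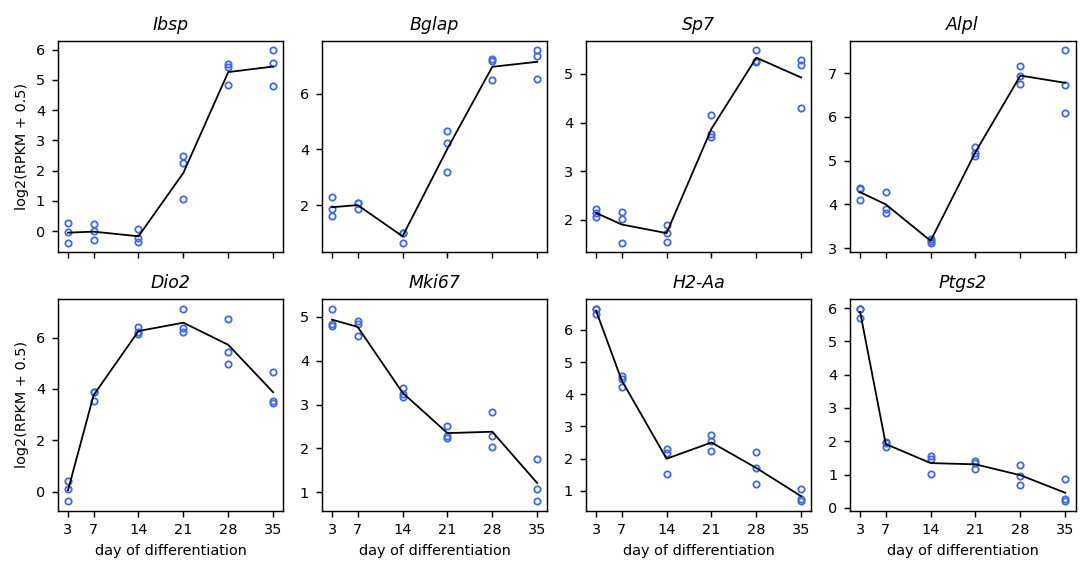
Level of 8 genes in untreated cells by day of differentiation (x axis), as log2(RPKM + 0.5) on the y axis, with 1 circle per library and a line through the daily means (n = 3 per day). *Ibsp*, *Bglap*, *Sp7* and *Alpl* rise from day 21, *Dio2* peaks at 98.7 RPKM on day 21, and *Mki67*, *H2-Aa* and *Ptgs2* fall.

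Immediate-early genes had moved by day 7, the first day sampled after day 3: 18 of 22 were lower than at day 3 and none higher (18 and none adjusted over the list alone, camera adjusted p = 1.07e-16, adjusted p = 0.0271 with an estimated correlation). The medians of other lists also lay off the all-gene median at day 7, such as tendon and muscle (−1.20), replication histone (−0.57) and vitamin D genes (0.67). Of 35 cell cycle genes 27 were lower at day 14 (30 adjusted over the list alone, 2.74e-14, adjusted p = 0.146 with an estimated correlation). Beside them 22 of 23 replication histones were lower (23 adjusted over the list alone, 2.87e-18, adjusted p = 0.0871 with an estimated correlation). Osteoblast genes moved at day 21, with 11 of 21 higher and 1 lower (the same adjusted over the list alone, 0.00033, adjusted p = 0.485 with an estimated correlation). Against day 3, 2551 genes differed at day 7 (1574 higher, 977 lower), 2954 at day 14 (1430 and 1524), 3671 at day 21 (1280 and 2391) and 4125 at day 28 (1029 and 3096). In all 7202 differed on any day. Quantile normalization gave 1663 higher and 1571 lower at day 7, and centring 2661 and 2150 at day 21 and 2847 and 2180 at day 28. The day 7 count depended on single libraries, at 1378, 1499 and 1614 without day 3 replicate 1, 2 or 3 and 1658 without day 7 replicate 3. Of 5573 genes called on any day in centred libraries, 1846 (33.1%) were highest on day 3 and 1316 (23.6%) on day 35, while 2511 (45.1%) were lowest on day 3 and 1019 (18.3%) on day 35.

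**Figure D2:**
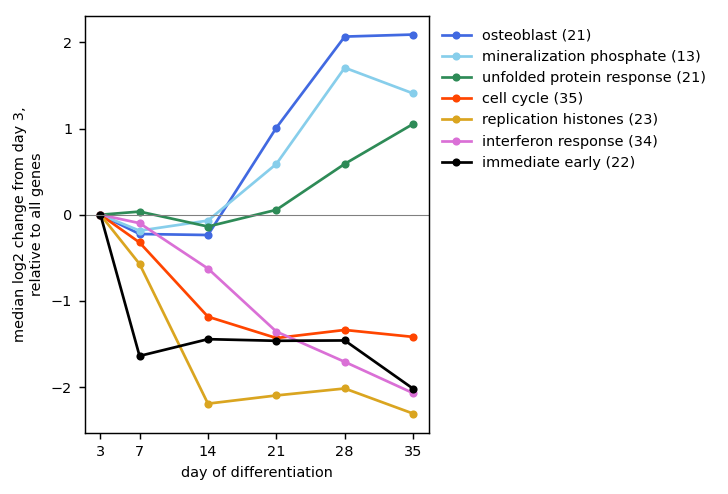
Median log2 change from day 3, relative to the median of all genes (y axis), of 7 gene lists in untreated cells by day (x axis), with the number of genes tested in brackets. The osteoblast list reaches 2.09 and the interferon list −2.07 at day 35, and the immediate-early list stands at −1.64 at day 7 and −2.02 at day 35.

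From each sampling day to the next few genes passed. The secreted Wnt regulator *Sfrp4* rose from 1.68 ± 0.257 RPKM at day 7 to 13.3 ± 1.80 at day 14 (n = 3 and 3, log2 change 2.66 ± 0.28, all-gene median −0.13). *Bglap* (3.13 ± 0.33) and *Sp7* (2.15 ± 0.25) rose from day 14 to day 21. *Panx3* (3.72 ± 0.35) and *Ibsp* (3.33 ± 0.34) rose from day 21 to day 28, and *Trib3* (2.36 ± 0.54) from day 28 to day 35. The *Trib3* rise did not pass with the run in the model (3.01, adjusted p = 0.128), without day 28 replicate 1 (1.35, adjusted p = 0.0726) or without day 35 replicate 2 (2.02, adjusted p = 0.0699). The count was 285 at the first of these steps (43 higher, 242 lower), 63 at the next (27 and 36), 123 after that (82 and 41) and 793 at the last (15 and 778). With the replicate number as a block the steps from day 14 on gave more genes, as listed under the dependence on processing. Centring the libraries gave 205 higher and 330 lower, 142 and 63, 197 and 77, and 126 and 203. Within 1 sequencing run, where replicates 2 and 3 of days 14, 21 and 28 were together, the middle steps gave 57 higher and 656 lower genes and 99 and 619. With the run in the model the last step gave 7 higher and 16 lower genes, 18 of them among the 793.

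The step counts also rested on single libraries. The *Sfrp4* step fell from 285 to 179 genes without day 7 replicate 2, 159 without day 7 replicate 3 and 180 without day 14 replicate 1. The step that brought *Bglap* gave 27 and 29 genes without day 14 replicate 2 or 3, 13 and 30 without day 21 replicate 2 or 3, and 123 without day 28 replicate 1, which shares the model only. For the *Panx3* step the values were 78 and 66 without day 21 replicate 1 or 3, and 400, 68 and 66 without day 28 replicate 1, 2 or 3. The *Trib3* step ran from 74 genes without day 28 replicate 1 to 2347 without day 35 replicate 1, with 1668, 259, 193 and 151 without day 28 replicate 2 or 3 and day 35 replicate 2 or 3.

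Vehicle-treated cells of the second experiment also gained bone transcripts by day 35, those of osteocyte genes among them. *Dmp1* rose from 5.63 ± 1.50 CPM at day 3 to 182 ± 58.4 CPM at day 35 (n = 3 and 3, log2 change 5.01 ± 0.28, all-gene median 0.17). *Phex* went from 37.1 ± 1.47 to 266 ± 42.0 (2.84 ± 0.16) and *Ibsp* from 38.1 ± 7.24 to 14272 ± 3015 (8.55 ± 0.25). *Sost* and *Mepe* had 0 counts in the day 3 libraries and 458 and 146 counts at day 35, a rise of at least 228-fold and at least 72.6-fold. *Bmp3* (10.76 ± 0.33, from 10 counts to 12055), *Galnt3* (10.29 ± 0.34), *Col13a1* (10.91 ± 0.50), *Kcnk1* (10.79 ± 0.63) and *Prex1* (9.74 ± 0.40) were among the largest changes. The Wnt antagonist genes *Wif1* (9.09 ± 0.57) and *Dkk1* (5.96 ± 1.20) rose with *Smpd3* (5.31 ± 0.20), *Bglap* (6.37 ± 0.33), *Sp7* (3.52 ± 0.23) and *Acan* (6.25 ± 0.38). *Trib3* (5.90 ± 0.37), *Spp1* (3.05 ± 0.22), the hypoxia gene *Pdk1* (3.20 ± 0.16) and the vitamin D receptor gene *Vdr* (1.57 ± 0.36) were higher too. *Fgf23* was all but absent at both days, with 3 counts and 1 count.

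Proliferation and interferon transcripts fell in the vehicle-treated cells as well. There, time since interferon-gamma and the expansion temperature ended is likewise not separable from differentiation. *Mki67* went from 697 ± 132 CPM at day 3 to 34.8 ± 11.4 at day 35 (n = 3 and 3, −4.32 ± 0.26). *Ptgs2* went from 1713 ± 168 to 26.7 ± 9.81 (−6.00 ± 0.25) and *H2-Eb1* from 493 ± 103 to 5.90 ± 1.69 (−6.38 ± 0.28). *Ifi27l2a* (−6.81 ± 0.34), *Rsad2* (−4.74 ± 0.19), *Maff* (−3.47 ± 0.17) and *Enpp3* (−2.24 ± 0.47) fell. *Tnfsf11*, which codes for RANKL, did not pass (−0.27 ± 0.24, adjusted p = 0.421), except without day 35 replicate 1 (−0.67, adjusted p = 0.0217). The small nuclear RNA genes *Rnu1b1* and *Rnu1b2* (−6.49 ± 0.46 and −6.48 ± 0.46) are copies with nearly the same counts and cannot be told apart here. *Rprl1* passed on 1 library alone (53.5 ± 92.6 CPM at day 35). Of 20055 genes tested, 6006 differed, 3101 higher and 2905 lower.

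Most gene lists moved between vehicle day 3 and day 35. Osteoblast genes rose in 17 of 23 against 2 falls (18 and 2 adjusted over the list alone, camera adjusted p = 1.31e-20) and osteocyte genes in 13 of 20 against 3 (the same adjusted over the list alone, 3.88e-05). Mineralization genes rose in 13 of 20 against 2 (14 and 2 adjusted over the list alone, 2.55e-18) and unfolded protein response genes in 19 of 23 against 1 (20 and 1 adjusted over the list alone, 1.34e-11). Glycolysis and hypoxia genes rose in 16 of 22 against 3 (the same adjusted over the list alone, 1.48e-08). Chondrocyte genes gained 7 of 15 against 1 (0.000193), and vitamin D genes 10 of 25 against 2 (0.000287). The tendon and muscle list lost 5 of 12 against 2 rises (0.000192), and these 3 lists were unchanged when adjusted over the list alone. Falls took 33 of 35 cell cycle genes (34 adjusted over the list alone, 6.96e-55), 39 of 41 interferon genes (41 adjusted over the list alone, 1.08e-56) and 21 of 22 immediate-early genes (21 adjusted over the list alone, 2.17e-29).

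Further lists were called at vehicle day 35 with the preset correlation only. Ribosomal protein genes rose in 22 of 24 (23 adjusted over the list alone, camera adjusted p = 1.63e-05, adjusted p = 0.418 with an estimated correlation). Wnt pathway genes rose in 16 of 36 and fell in 6 (17 and 8 adjusted over the list alone, 0.000562, adjusted p = 0.0742 with an estimated correlation). Replication histones fell in 23 of 24 (24 adjusted over the list alone, 1.62e-20, adjusted p = 0.0872 with an estimated correlation) and cholesterol synthesis genes in 15 of 19 (16 adjusted over the list alone, 1.63e-05, adjusted p = 0.171 with an estimated correlation). Inflammatory genes fell in 10 of 21 against 3 rises (10 and 3 adjusted over the list alone, 4.12e-05, adjusted p = 0.0532 with an estimated correlation). Collagen and matrix genes (14 of 34 higher, 8 lower), matrix proteases (11 and 7 of 27), the BMP and TGF-beta pathway (8 and 11 of 31), and axon guidance genes (11 and 8 of 28) did not move as sets. Nor did oxidative phosphorylation (1 and none of 24), adipocyte (5 and none of 16), macrophage and osteoclast (2 and 3 of 11), endothelial (none and 1 of 8) and nuclear noncoding genes (5 and 1 of 20).

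At day 35, 1,25(OH)2D3 raised its degrading enzyme gene *Cyp24a1* from 4 counts in the 3 vehicle libraries to 10285, or from 0.0474 ± 0.0222 to 78.4 ± 20.4 CPM (n = 3 and 3, log2 change 10.62 ± 0.45, all-gene median 0.02). *Spp1* (osteopontin) rose from 287 ± 32.0 to 3386 ± 586 CPM (3.56 ± 0.22) and *Tnfsf11* (RANKL) from 8.19 ± 3.38 to 91.4 ± 12.2 (3.48 ± 0.26). The gene of its decoy receptor, *Tnfrsf11b*, fell (−1.70 ± 0.30). The pyrophosphate-generating *Enpp1* (7.49 ± 3.90 to 47.3 ± 4.01 CPM, 2.65 ± 0.29) and its relative *Enpp3* (5.32 ± 0.48), the Wnt inhibitor gene *Notum* (3.42 ± 0.22), *Vdr* itself (1.64 ± 0.35) and *Mmp13* (1.11 ± 0.19) were induced. *Fbln7* (2.35 ± 0.14), *Bdkrb2* (5.07 ± 0.45), *Serpina12* (5.24 ± 0.62), *Tesc* (6.65 ± 0.90) and *Ankrd55* (7.23 ± 0.91) rose as well. *Bhmt* went from 1 count to 903, a ratio of 601 with a counting interval of 108 to 23777, and for *Cyp24a1* the ratio was 1712 (669 to 6285). The rise of *Vdr* did not pass without vehicle replicate 3 (1.49, adjusted p = 0.062) or hormone replicate 3 (1.51, adjusted p = 0.053).

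*Ibsp*, *Sp7* and other osteoblast genes fell with 1,25(OH)2D3 at day 35. *Ibsp* dropped from 14272 ± 3015 to 5452 ± 334 CPM (n = 3 and 3, −1.39 ± 0.19) and *Sp7* from 76.4 ± 12.8 to 27.8 ± 4.45 (−1.46 ± 0.21). *Smpd3* dropped from 202 ± 7.86 to 30.1 ± 0.840 (−2.75 ± 0.17) and *Prss35* from 706 ± 23.6 to 106 ± 24.3 (−2.74 ± 0.18). *Slc13a5* (−2.83 ± 0.32), *Cspg4* (−2.82 ± 0.25), *Adamts18* (−2.77 ± 0.31) and *Wnt10b* (−1.98 ± 0.28) fell too. *Acan* (−2.01 ± 0.30), *Tnc* (−1.49 ± 0.15), *Klf4* (−1.75 ± 0.26) and the chaperone gene *Hspa5* (−1.24 ± 0.16) were also lower. *Phex* was lower (−0.76 ± 0.15), although not without vehicle replicate 2 (−0.59, adjusted p = 0.0883) or hormone replicate 1 (−0.60, adjusted p = 0.0695). *Dmp1* (0.48 ± 0.23, adjusted p = 0.364), *Bglap* (−0.31 ± 0.26, adjusted p = 0.702) and *Col1a1* (−0.50 ± 0.33, adjusted p = 0.585) did not differ. *Alpl* (−0.91 ± 0.25, adjusted p = 0.0533) and *Sost* (458 counts with vehicle, 32 with hormone, −4.42 ± 1.19, adjusted p = 0.0563) did not pass, although both passed in centred libraries (adjusted p = 0.0431 and 0.0444). In all 914 of 20055 genes differed, 484 higher and 430 lower, and 589 without vehicle replicate 2.

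The vitamin D list answered at day 35 with 9 of 25 genes higher and 2 lower (9 and 3 adjusted over the list alone, camera adjusted p = 6.61e-16). Interferon genes, low at this age, rose in 10 of 41 with none lower (12 and 1 adjusted over the list alone, 9.64e-12). Among them were *Rsad2* (2.61 ± 0.127 to 20.7 ± 3.55 CPM, n = 3 and 3, 2.99 ± 0.18) and *Gbp3* (1.72 ± 0.16). Inflammatory genes rose in 4 of 21 with none lower (5 and none adjusted over the list alone, 4.58e-07), among them *C3* (3.76 ± 0.35), *Ptges* (2.14 ± 0.13) and *Il1rl1* (2.27 ± 0.27). Osteoblast genes fell in 5 of 23 against 1 rise (11 and 1 adjusted over the list alone, 6.06e-06). The mineralization and phosphate list, with 6 of 20 higher and 4 lower (6 and 9 adjusted over the list alone, 0.827), did not move as a set. Unfolded protein response genes fell in 12 of 23 with none higher (18 and 1 adjusted over the list alone, 7.63e-15). Collagen and matrix genes (5 lower and 3 higher of 34, 10 and 3 adjusted over the list alone, 0.00519, adjusted p = 0.602 with an estimated correlation) were called at the preset correlation only. The same held for cell cycle genes (3 lower of 35, 8 adjusted over the list alone, 2.67e-05, adjusted p = 0.217 with an estimated correlation). Glycolysis genes were the last of this kind (3 lower of 22, 7 lower and 1 higher adjusted over the list alone, 0.00313, adjusted p = 0.0843 with an estimated correlation).

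**Figure D3:**
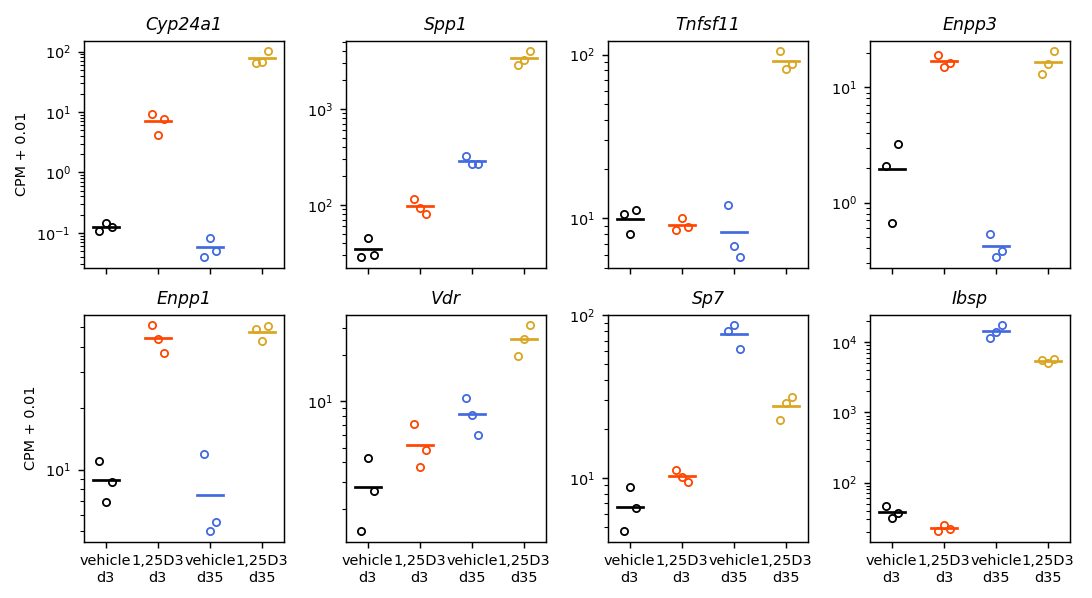
Level of 8 genes in the 4 groups of the hormone experiment (x axis, n = 3 per group), as CPM plus 0.01 on a log y axis, with 1 circle per library and a bar at the group mean. *Cyp24a1* reaches 78.4 CPM with 1,25(OH)2D3 at day 35 and 6.99 at day 3, *Tnfsf11* is induced at day 35 only, and *Sp7* and *Ibsp* fall at day 35.

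At day 3 *Cyp24a1* and *Spp1* were induced to lower levels than at day 35, while *Enpp3* reached 16.8 CPM at day 3 and 16.5 CPM at day 35. *Cyp24a1* rose from 0.116 ± 0.0189 to 6.99 ± 2.55 CPM (n = 3 and 3, log2 change 5.87 ± 0.37, all-gene median 0.26). *Enpp3* went from 1.96 ± 1.27 to 16.8 ± 2.01 (3.09 ± 0.41) and *Enpp1* from 8.91 ± 2.06 to 44.1 ± 6.87 (2.31 ± 0.29). *C3* went from 0.844 ± 0.533 to 45.4 ± 12.9 (5.74 ± 0.41) and *Spp1* from 34.6 ± 9.36 to 96.3 ± 18.4 (1.48 ± 0.21). *Bhmt* went from 2 counts to 549, a ratio of 354 (97.4 to 2926), where background would give 20.4, 19.0 and 26.2 counts in the 3 hormone libraries. *Fbln7* (1.29 ± 0.14), *Matn3* (1.80 ± 0.27) and *Ddit4* (2.30 ± 0.23) rose. *Tnfsf11* did not move (−0.12 ± 0.24, adjusted p = 0.72) and *Vdr* did not pass (0.91 ± 0.36, adjusted p = 0.0774). *Vdr* did pass without vehicle replicate 2 (1.37, adjusted p = 0.0224), with the stricter filter (1.11, adjusted p = 0.0485), without scaling beyond library size (1.31, adjusted p = 0.0325) and in DESeq2 (0.99, adjusted p = 0.0383). *Dmp1* (−1.51 ± 0.27), *Pdpn* (−1.14 ± 0.21), *Phex* (−0.71 ± 0.15), *Ibsp* (−0.76 ± 0.19) and *Tnfrsf11b* (−2.12 ± 0.31) were lower. The falls of *Phex* (−0.32, adjusted p = 0.147) and *Ibsp* (−0.37, adjusted p = 0.083) did not pass without scaling beyond library size. That of *Ibsp* did not pass without hormone replicate 3 either (−0.75, adjusted p = 0.057).

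Large falls with 1,25(OH)2D3 at day 3 included those of immediate-early genes. *Ctgf* dropped from 1502 ± 712 to 13.2 ± 3.42 CPM (n = 3 and 3, −6.83 ± 0.35). *Ptgs2* dropped from 1713 ± 168 to 21.5 ± 0.435 (−6.31 ± 0.25) and *Thbs1* from 18165 ± 1990 to 1916 ± 148 (−3.25 ± 0.18). *Nr4a1* (−6.09 ± 0.58), *Atf3* (−5.41 ± 0.22), *Hbegf* (−5.24 ± 0.26), *Rgs16* (−5.11 ± 0.38), *Maff* (−5.03 ± 0.19) and *Inhba* (−4.30 ± 0.22) followed. *Cyr61* (−3.55 ± 0.18), *Timp3* (−2.77 ± 0.21), *Adm* (−2.25 ± 0.19), *Hk2* (−2.19 ± 0.19), the tendon factor gene *Scx* (−2.24 ± 0.20) and *Acta2* (−1.41 ± 0.20) were lower as well. *Mki67* did not differ (−0.25 ± 0.23, adjusted p = 0.424).

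Of 20055 genes tested at day 3, 4102 differed with 1,25(OH)2D3, 2278 higher and 1824 lower. Of the 2278 higher genes 1571 (69.0%) had under 1 CPM with vehicle. The same hormone libraries held reads on 1100 olfactory receptor genes at a sum of 645.8 ± 124.7 CPM, where vehicle had 45.6 ± 8.58 (n = 3 and 3). With that background taken off per kilobase, a step chosen after the data were seen, 1495 genes were higher and 1386 lower. Other scalings gave 2255 higher and 3638 lower (centred libraries) or 4228 and 594 (library size alone). The count was 1727, 2025 and 2508 without hormone replicate 3, 2 or 1 and 2632 without vehicle replicate 2. It was 6185 and 7328 without day 35 hormone replicate 1 or 2, which share the model but not the comparison. *Adipoq*, the gene with the largest listed rise, had 16, 4 and 1052 counts in the 3 hormone libraries, and its group mean stands for replicate 3 alone. *Mepe* (10, 7 and 13 counts), *Sost* (16, 18 and 1) and *Dkk1* (49, 36 and 36) also passed from 0, 0 and 9 counts with vehicle, at levels that background alone would give for *Mepe* and *Sost*. With background subtracted *Sost* (4.88, adjusted p = 0.118) and *Dkk1* (3.78, adjusted p = 0.0841) did not pass.

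Immediate-early genes fell in 21 of 22 at day 3 with 1,25(OH)2D3 (21 adjusted over the list alone, camera adjusted p = 2.54e-64). Glycolysis and hypoxia genes fell in 11 of 22 (11 adjusted over the list alone, 3.51e-08). The BMP and TGF-beta pathway fell in 13 of 31 against 4 rises (14 and 4 adjusted over the list alone, 5.19e-11) and tendon and muscle genes in 6 of 12 (6 adjusted over the list alone, 3.4e-05). Collagen and matrix genes (11 of 34 lower, 20 adjusted over the list alone, 5.19e-11, adjusted p = 0.104 with an estimated correlation) were called at the preset correlation only. So were matrix proteases (8 of 27 lower and 1 higher, 12 and 1 adjusted over the list alone, 1.08e-08, adjusted p = 0.0726 with an estimated correlation) and inflammatory genes (7 of 21 lower and 3 higher, 8 and 3 adjusted over the list alone, 6.67e-05, adjusted p = 0.104 with an estimated correlation). Unfolded protein response genes (9 of 23 lower and 1 higher, 12 and 1 adjusted over the list alone, 8.14e-07, adjusted p = 0.114 with an estimated correlation) and interferon genes (5 of 41 lower, 3 adjusted over the list alone, 0.00983, adjusted p = 0.114 with an estimated correlation) were of this kind too. With adjusted p = 0.338 with an estimated correlation the same held for oxidative phosphorylation (5 of 24 lower, 7 adjusted over the list alone, 0.000135), cholesterol synthesis (4 of 19, 4 adjusted over the list alone, 0.000592) and cell cycle genes (3 of 35, 3 adjusted over the list alone, 0.00219). Ribosomal protein genes (1 of 24 lower, none adjusted over the list alone, 0.00125, adjusted p = 0.484 with an estimated correlation) and axon guidance genes (5 of 28 lower and 1 higher, 6 and 2 adjusted over the list alone, 0.0372, adjusted p = 0.426 with an estimated correlation) completed these calls. The vitamin D list, with 5 of 25 genes higher and 5 lower (7 and 5 adjusted over the list alone, 0.211), did not move as a set. Nor did the osteoblast list, with 3 of 23 higher and 5 lower (5 and 6 adjusted over the list alone, 0.211).

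**Figure D4:**
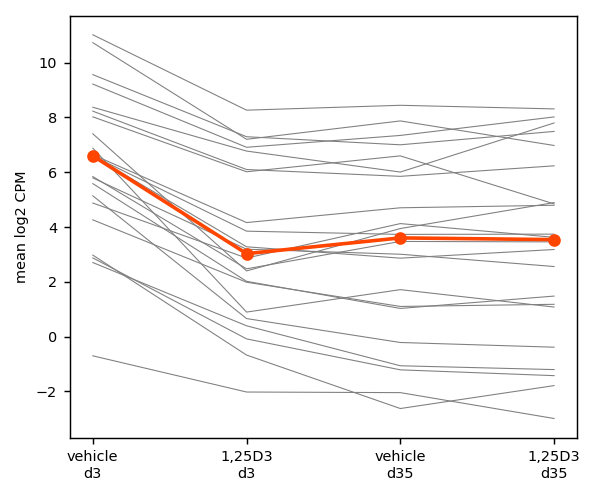
Mean log2 CPM (y axis) of 22 immediate-early genes in the 4 groups of the hormone experiment (x axis, n = 3 per group), with 1 grey line per gene and their median in orange. Gene by gene, the median difference was −2.68 for 1,25(OH)2D3 against vehicle at day 3 and −2.82 for vehicle day 35 against vehicle day 3. These are not the falls of the orange line, which joins the median levels of the 4 groups.

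Large upward differences between the responses were found in genes that fell at day 3. *Ctgf* (difference of log2 changes, day 35 minus day 3, 8.28 ± 0.43), *Ptgs2* (6.50 ± 0.31), *Maff* (6.00 ± 0.24), *Il1rl1* (5.07 ± 0.38) and *Hbegf* (5.59 ± 0.33) were in this class (n = 3 in each of 4 groups, all-gene median −0.29). Vehicle levels of these genes were already lower at day 35, such as *Ptgs2* at 26.7 CPM against 1713 at day 3. Hormone targets with the larger log2 change in late cells were *Cyp24a1* (4.76 ± 0.76), *Tnfsf11* (3.60 ± 0.34), *Notum* (3.57 ± 0.30), *Spp1* (2.08 ± 0.29) and *Enpp3* (2.22 ± 0.60). With hormone *Enpp3* stood at 16.8 CPM at day 3 and 16.5 at day 35, while its vehicle level went from 1.96 to 0.406 CPM. *Rsad2* fell at day 3 (−1.20 ± 0.16) and rose at day 35, a difference of 4.19 ± 0.24. *Enpp3* lost its call in 7 fits that each left out 1 library, such as day 3 vehicle replicate 3 (1.82, adjusted p = 0.0637), after quantile normalization (1.87, adjusted p = 0.106) and without scaling beyond library size (1.85, adjusted p = 0.0727). *Sp7* (−2.09 ± 0.31) and *Smpd3* (−2.27 ± 0.24) fell in late cells alone, and *Dmp1* (1.99 ± 0.35) and *Pdpn* (1.64 ± 0.30) in early cells alone. *Sost* (−11.18 ± 2.16), *Mepe* (−8.29 ± 1.64), *Dkk1* (−7.36 ± 1.53), *Robo2* (−7.22 ± 1.31) and *Fut9* (−6.83 ± 1.90) also passed. Each had at most 10 counts in every day 3 vehicle library, and the day 3 hormone libraries carried background. The difference of *Mepe* did not pass with background subtracted (−2.10, adjusted p = 1.00) or quantile normalization (−1.78, adjusted p = 0.259). That of *Fut9* was lost in 11 fits, such as the robust variance estimate (adjusted p = 0.0737).

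In total 1420 of 20055 genes differed in their response, 831 upward and 589 downward, or 1356 and 458 in centred libraries and 481 and 1481 without scaling beyond library size. The count was 925 without day 3 hormone replicate 3 and 4890 without day 35 hormone replicate 2, the late library with the most reads on olfactory receptor genes (424 CPM). Of 100 assignments of the treatment labels within each day 5 gave as many genes, the real one included. Immediate-early genes were higher in the difference in 18 of 22 (20 adjusted over the list alone, camera adjusted p = 1.49e-60), and interferon genes in 10 of 41 (12 adjusted over the list alone, 8.96e-11). Vitamin D genes were higher in 7 of 25 (8 adjusted over the list alone, 7.92e-05), matrix proteases in 8 of 27 with 1 lower (12 and 1 adjusted over the list alone, 8.96e-11) and inflammatory genes in 8 of 21 with 1 lower (10 and 3 adjusted over the list alone, 1.79e-11). Each of these lists kept its call with an estimated correlation. Further lists called upward did not, among them the BMP and TGF-beta pathway (10 of 31 higher and 5 lower, 12 and 6 adjusted over the list alone, 4.15e-07, adjusted p = 0.0704 with an estimated correlation) and collagen and matrix genes (5 of 34 higher, 7 higher and 2 lower adjusted over the list alone, 6.69e-05, adjusted p = 0.281 with an estimated correlation).

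Across genes, differentiation looked alike in the 2 experiments. The day 35 against day 3 changes of untreated and vehicle-treated cells correlated at r = 0.76 (rho = 0.72, 9372 genes, which are not independent replicates). Of 2767 genes called in both 89.6% had the same sign, or 97.3% in centred libraries. Both experiments raised 440 genes, such as *Ibsp* and *Bglap*, where 106 would be shared by chance, and lowered 2040, such as *Mki67*, where 1124 would be. The 1,25(OH)2D3 responses of day 3 and day 35 shared 147 higher genes, among them *Cyp24a1*, *Enpp1* and *Spp1* (55.0 by chance), and 143 lower ones, among them *Tnfrsf11b* and *Ibsp* (39.1 by chance). A further 83 genes, *Rsad2* among them, were lower at day 3 and higher at day 35 (44.0 by chance), and 28.6% of the 406 genes called at both days had opposite signs. Over 20055 genes r was 0.27 (rho = 0.34) and became −0.44 without day 35 hormone replicate 2, when 139 higher genes were shared (96.8 by chance) and 37.1% of the genes called at both days had opposite signs. With the stricter filter r was 0.27, and 0.0317 without that library. Genes lowered by 1,25(OH)2D3 at day 35 included 75 of the genes that untreated cells raised by day 35, among them *Ibsp*, *Sp7*, *Smpd3* and *Prss35*, where 17.4 would be by chance. In centred libraries the overlap was 158 genes against 92.9 by chance. Over all 9372 genes that correlation was weak (r = −0.12, rho = −0.09), and 64.4% of 416 genes called in both had opposite signs.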

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

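The tests in this part were chosen after the results they bear on had been seen, and their predictions were written down after the values.

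With 1,25(OH)2D3 at day 3, 1571 of the 2278 genes called higher lay under 1 CPM with vehicle. Background spread over the transcripts could produce many of them. Of those with a known length, 70.0% rose by an amount within 4-fold of what the reads on olfactory receptor genes predict. The median rise was 2.55 times that prediction (quartiles 1.59 and 4.53). Olfactory receptor genes were not taken out of the genes counted, so any among them fit the prediction in part by construction. RNA of any of the 10 tissues tested is ruled out as the whole source in all 3 libraries, though not that of other tissues, since the best of the 10 had markers at only 2.44 times background in its lowest library. Among the day 3 hormone libraries, fat markers stood far above background in replicate 3 alone, with 3740 counts of *Fabp4* and 982 of *Cidec*. Beyond the fat markers, *Dmbt1* (58, 27 and 835 counts) and *Amy2a5* (101, 44 and 642) were also highest in that replicate. In the day 35 libraries the median fat marker lay at 16.5 to 486 times background. An effect of the hormone on the 1571 genes stays open. At day 35 2.29% of them were also called higher, but a response of early cells alone would not show there.

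The 22 immediate-early genes had a median change of −2.68 with 1,25(OH)2D3 at day 3. Dilution by background reads is ruled out, because background took at most 1.10% of the reads. Day 35 cells under a day 3 label are ruled out too, since the cell cycle list had a median of −0.25 there. Cells only slightly past day 3 cannot be excluded by it, because in untreated cells that list moved by only −0.0959 from day 3 to day 7. Whether a difference in handling or in time since feeding contributed cannot be told, because no label records either. The immediate-early list moved by −1.41 from day 3 to day 7 in untreated cells. That shows a fall without the hormone, but it does not separate handling from treatment at day 3. A direct effect of the hormone is not excluded, but at day 35, where the immediate-early list is already low, its median was −0.0844.

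Most genes called between untreated day 3 and day 35 were lower, with a median of −0.69. A larger rRNA share could explain part but not all of it, since the median stayed at −0.36 after rescaling to the other rows. Day 35 replicate 3 (−0.54 without it) and the sequencing run (−0.40 with it in the model) likewise leave most of the shift. Less mRNA per cell at day 35 remains open, because the tables hold 0 rows of spike-in RNA.

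For pairs of groups with 3 libraries each, 10 splits cannot give a share under 0.05. In untreated cells the real split was the only 1 to reach its count for day 35 against day 3 (5676 genes, highest other 0), day 7 (2551, highest other 1), day 14 (2954, highest other 1), day 21 (3671, highest other 1) and day 28 against day 3 (4125, highest other 1), for day 14 against day 7 (285, highest other 0), day 21 against day 14 (63, highest other 0) and day 28 against day 21 (123, highest other 2). For day 35 against day 28, 2 splits reached the real count of 793. The other, with replicate 1 of both days and day 28 replicate 3 on a side, gave 2254 genes and points to a structure of the samples. It follows the sequencing run in part, and with the run in the model 23 genes were called. In the hormone experiment the real split stood alone for 1,25(OH)2D3 at day 3 (4102 genes), at day 35 (914) and vehicle day 35 against day 3 (6006), each with a highest other count of 0.

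Over the 6 days of untreated cells, 1 of 100 assignments reached the real count of 7202, the real one, with 3297 as the highest other. For the difference between the 1,25(OH)2D3 responses, 5 of 100 assignments of the treatment labels within each day reached 1420 genes. The real assignment was among them, and the highest other gave 5362. All 4 others kept the true labels of day 3 and moved or exchanged those of day 35 alone, so each still held the day 3 response of 4102 genes. With the day 3 labels mixed the highest count was 132. By this count chance is not excluded, but it bears little on whether the responses differ.

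Genes picked for a difference between the responses had these values. Higher at day 35 were *Ctgf* 8.28, *Ptgs2* 6.50, *Maff* 6.00, *Trib1* 5.70, *Nr4a1* 5.66, *Hbegf* 5.59 and *Rgs16* 5.53, with *Cyp24a1* 4.76, *Tnfsf11* 3.60, *Enpp3* 2.22, *Spp1* 2.08, *Dmp1* 1.99 and *Pdpn* 1.64. Lower were *Sost* −11.18, *Adipoq* −10.57, *Mepe* −8.29, *Dkk1* −7.36, *Lars2* −7.26, *Robo2* −7.22, *Gpr133* −7.04, *Ptprz1* −7.00, *Fut9* −6.83, *Chi3l1* −6.47 and *Sp7* −2.09. *Adipoq* did not pass with background subtracted (adjusted p = 0.0714) or in 11 other fits. *Lars2* rests on 2 libraries, with 46163 counts in day 35 vehicle replicate 2 and 12264 in day 3 hormone replicate 2. Lists picked in the same way stood above the median of all genes by 3.00 (immediate-early), 1.37 (inflammatory), 0.97 (interferon), 0.95 (matrix protease) and 0.71 (vitamin D).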

How the results depend on the processing

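The filter and the threshold moved most counts. The stricter filter gave 2148 genes for untreated day 35 against day 3, 1255 at day 7, 1290 at day 14, 1483 at day 21 and 1486 at day 28, 161 for day 14 against day 7, 60 for day 28 against day 21, 3072 on any day and 2441 for 1,25(OH)2D3 at day 3. A log2 change of at least 1 left 3758, 1192, 1546, 2156 and 2544 genes against day 3, 366 for day 35 against day 28, 2483 and 554 for 1,25(OH)2D3 at day 3 and 35, and 3822 for vehicle day 35 against day 3. The threshold lowers counts by construction. The stricter filter tests fewer genes (10120 in the hormone experiment, where the main filter left 20055). It thus drops calls among genes no longer tested. It need not lower a count, and gave 1169 genes for 1,25(OH)2D3 at day 35 (914).

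Steps between neighbouring days moved most. Day 14 against day 7 (285) became 535 in centred libraries, 594 with quantile normalization and 489 rescaled to rows other than rRNA. Day 21 against day 14 (63) gave 41 with a pseudocount of 0.1, 205, 223 and 228 with those scalings, 148 with the run, 16 with the groups compared alone and 713 within 1 run. Day 28 against day 21 (123) gave 274, 291, 390, 247, 52 and 718. Day 35 against day 28 (793) gave 1256 with a pseudocount of 0.1, 528 without a filter, 329 and 326 with the scalings, 23 with the run and 89 with the groups alone. Day 35 against day 3 gave 3463 with the run, 3254 of them shared. The cause was not tested.

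The replicate number as a block gave 128, 213 and 1502 genes for the last 3 steps, and *Spp1* passed with it at day 35 against day 3 (adjusted p = 0.0492). Residuals of untreated libraries with the same number correlated above 0.1 in 41 of 45 pairs, but only 29 were best with their own number, against 2 and 4 of 18 pairs in the hormone experiment, so the numbers were not taken as pairs, though they hint at shared structure in the untreated libraries.

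For 1,25(OH)2D3, DESeq2 gave 6412 genes at day 3, 1588 at day 35 and 2715 for the difference, and the day 35 groups alone 1402. The correlation of the differentiation changes was 0.51 without a filter and 0.88 with the stricter one, and that of the day 35 response with differentiation was −0.0135 without a filter. List calls numbered 62, and 25 with an estimated correlation.

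Leaving out 1 library at a time gave 1378 to 2850 genes at day 7, 159 to 353, 13 to 123, 66 to 400 and 74 to 2347 for the 4 steps, 1727 to 7328 for 1,25(OH)2D3 at day 3, 589 to 1137 at day 35 and 925 to 4890 for the difference. The correlation of the 2 responses ran from −0.44 to 0.41, negative without day 35 hormone replicate 2. Without that library r was 0.0317 with the stricter filter and 0.0717 with background subtracted as well, so the negative value went with genes of low level. For the other changes the cause was not tested.

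Among gene-level values, settings fixed before the data were examined left 3414 the same, 86 weaker, 16 stronger and 3 reversed, and those chosen later 974, 9, 7 and 1. Those that reversed were *Mepe* with 1,25(OH)2D3 at day 3 (−0.26 with quantile normalization, 0 with background subtracted), *Sost* there (−0.0432 with quantile normalization) and *Chi3l1* in the difference (0.49 with quantile normalization). Leaving out libraries of other groups, rescaling to other rows, size factors, DESeq2 and background subtraction were chosen after the data were seen.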

Other observations

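Tests named in this part were chosen after the results were seen.

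The deiodinase gene *Dio2* led the early rises in untreated cells, beside the protocadherin gene *Pcdh20* (1.13 ± 0.205 RPKM at day 3, 19.0 ± 0.720 at day 7, n = 3 and 3, log2 change 3.59 ± 0.28) and the angiotensin receptor gene *Agtr2* (0.293 ± 0.148 at day 3, 12.9 ± 1.62 at day 14, 4.09 ± 0.35). *Agtr2* then fell between day 21 and day 28 (−1.60 ± 0.35), when *Panx3* and *Ibsp* rose, and *Igf1* fell at the same step (−1.56 ± 0.36). The call of *Agtr2* was lost in 7 fits (adjusted p = 0.193 without day 28 replicate 2) and that of *Igf1* in 8 (adjusted p = 0.0603 in centred libraries). From day 14 to day 21 the activin subunit gene *Inhbb* fell (−1.52 ± 0.29), which did not pass in 4 fits that each left out 1 library (adjusted p = 0.147 without day 21 replicate 2).

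In late cells 1,25(OH)2D3 turned genes of several classes in ways not described above. *Dusp6* rose (65.1 ± 13.4 to 223 ± 21.1 CPM, n = 3 and 3, 1.78 ± 0.17), as did the sterol and sex steroid enzyme gene *Hsd17b7* (1.63 ± 0.18), *Lpl* (1.84 ± 0.27), *Matn3* (1.97 ± 0.26), *Fbn1* (1.13 ± 0.15), *Loxl2* (1.35 ± 0.25), *Wnt5a* (0.82 ± 0.15) and *Ntn1* (1.18 ± 0.18). *Bambi* (−1.23 ± 0.14), *Id2* (−1.37 ± 0.17), *Bmp3* (−1.36 ± 0.19), *Wisp1* (−0.87 ± 0.12), *Edem1* (−1.24 ± 0.13) and *Ddit3* (−1.29 ± 0.20) fell, although *Bmp3* did not pass with background subtracted (−1.34, adjusted p = 0.0723). With differentiation *Bambi* (2.12 ± 0.15) and *Ddit3* (2.84 ± 0.21) had risen in vehicle-treated cells, while *Id2* was at 111 CPM at day 3 and 31.7 CPM at day 35.

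Phosphate and pyrophosphate genes gave mixed responses. Both *Enpp1* and *Enpp3* rose with 1,25(OH)2D3 at both ages, while *Slc20a1* (−1.95 ± 0.18) and *Sgms2* (−1.43 ± 0.16) fell at day 3, and the pyrophosphate transporter gene *Ank* went from 40.3 to 17.7 CPM at day 3 and from 63.8 to 201 CPM at day 35 (difference 2.84 ± 0.37). The mean of *Sgms2* was also lower with hormone at day 35 (1065.6 ± 30.6 to 601.7 ± 109.1 CPM), for which no test is given here. The mineralization and phosphate list did not move as a set at day 35 (adjusted p = 0.827), and mineral was not measured.

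*Dmp1* was hard to see in untreated cells, at 0.152 to 0.556 RPKM in the 3 day 35 libraries, and plain in vehicle-treated cells, at 182 ± 58.4 CPM. The experiments used different kits, and 30.0% of the genes seen in day 3 vehicle cells were listed under 1 RPKM in untreated cells of that day, so absence in the untreated libraries is weak evidence.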
